A study of Brassica napus with 8 samples.

How the data were processed

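The series measured gene expression with a one-colour Agilent Brassica array in Brassica napus (oilseed rape) line DH12075. Per the labels' protocols, total RNA was isolated with the RNeasy plant mini kit from frozen siliques with developing seeds, 2 days after pollination, and Cy3-labelled cRNA was made with the Quick Amp kit. The series design speaks of developing seeds instead. The tissue label was followed, and what is said below of the silique wall and of the seed share rests on it. The labels give 2 genotypes with 4 arrays each, wild type and Bntt16 RNAi, plants in which RNA interference is directed at the rape homologues of TRANSPARENT TESTA16, a MADS-box transcription factor gene. The labels do not say whether the 4 samples of a group came from separate plants, so every p-value measures the spread between these samples.

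Per the file headers, each array was scanned at 532 nm and its spots were measured with GenePix Pro 6.0.1.27, with local background and no normalization. The deposited scanner values are foreground and background brightness in intensity units, with their pixel standard deviations in the same units. Per the file headers, 2 further columns are in percent: the share of saturated pixels, and the share of pixels brighter than the background plus 2 standard deviations. The submitters' processing notes name Agilent Feature Extraction 10.5.1.1 and the TAIR10 build instead, and the source of this difference is not given in the sources used here. The deposited series table is on a log2 scale: for bright spots it equalled the log2 background-subtracted signal plus a constant for each array (slope 1.00, correlation across spots 1.000), and its scaling rule and its handling of dim spots are not given in the sources used here. It was used as an alternative only.

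Each array had 45220 spots, of which 1417 were control spots, and the other 43803 spots held 43603 distinct probes. The test settled before the data were examined was limma on the processed signal of Feature Extraction, scaled to the 75th percentile of each array. The files hold no such column. In its place, normexp background correction with an offset of 50 was applied to the foreground and background medians of all spots, control spots were then left out, the arrays were quantile normalized, and spots of the same probe were averaged. A probe counted as well above background where the software had found the spot and its foreground minus background exceeded 2.6 times the background standard deviation. A probe was tested when this held on all 4 arrays of at least 1 group, which left 20829 probes. Probes with at least 50 percent saturated pixels were recorded. The number of arrays limits the precision.

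Gene names came only from the description column of the files, since no column linked the probes to the reference gene table, and no genome position is given for any gene. A description beyond the name of a sequence library was given for 16001 probes, and another 1172 shared a contig with a described probe. The other 26430 had no product description. An informative product name was carried by 9155 probes (21.0 percent), since descriptions such as uncharacterized protein were not counted as informative. Many descriptions give the protein of another species and a percent whose meaning is not given in the sources used here. No description named TRANSPARENT TESTA16 (0 probes), so the target of the RNAi has no value here. Among the genes selected by the rule below, 6 descriptions named bacterial, fungal or phage proteins at 3 to 8 percent, and 1 gave only an isoform of a database entry. These are not used as names. Names from plant proteins were kept at low percents too, such as lipoxygenase 2 (6 percent, the probe that passed), squalene monooxygenase (8 percent) and actin (14 percent, from banana).

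The comparison, Bntt16 RNAi minus wild type, used lmFit and eBayes of limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, Python 3.11.15 for annotation and figures) with group as the only term. P-values are two-sided, from limma's moderated test, and adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. A second count also required a change of at least 2-fold. Gene lists were settled before the data were examined, for flavonoid enzymes and transporters, flavonoid regulators, phenylpropanoid and lignin enzymes, MADS-box genes, seed coat mucilage, endosperm and seed size, nucellus and programmed cell death, embryo maturation and storage, fatty acid and triacylglycerol synthesis, gibberellin, auxin, photosynthesis, secondary wall, pollen and tapetum, heat shock, cold and drought, defence and jasmonate, glucosinolates, and the cell cycle. After the descriptions were seen and before any group was compared, their wording was adapted to the array, with homologues added. The 14 lists with at least 3 tested probes were tested with limma's camera (preset correlation 0.01), again with an estimated correlation, and with fry. List p-values are adjusted over the 14 lists.

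The genes named by list are up to 4 per list with the smallest adjusted p below the threshold, at 1 probe per gene, or up to 2 as values where none passed. Outside the lists they are the 10 largest rises and the 10 largest falls among informative names. Those probes passed the threshold, were well above background on all 8 arrays, were not saturated throughout a group, and had all 4 arrays of a group above all 4 of the other. Up to 5 more per direction are genes not above background on any array of a group, with the fold as a lower bound. Of the 25 families grouped by description, all were set up after the results by gene had been seen, and their camera p-values are adjusted over the 25.

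The replicate number is also the position of the array on its slide. Before any fit, the deviations of each array from its group mean were correlated between groups. The values for equal numbers were 0.74, 0.14, 0.36 and 0.28, all above the limit of 0.1, so the numbers were treated as pairing the samples and a fit with a replicate block was run. Among unequal numbers, wild type 2 with Bntt16 RNAi 3 (0.15) and wild type 4 with Bntt16 RNAi 3 (0.11) also exceeded it, and the others ran from −0.52 to 0.09. The unblocked fit stays the reference because it was settled first. All wild-type arrays lie on 1 slide and all Bntt16 RNAi arrays on the other, so slide and genotype cannot be told apart, and a slide term could not be fitted. On simulated arrays with the 20829 probes of this comparison, of which 200 were changed, 52 percent of the changes of log2 1 and 87 percent of those of log2 2 were recovered, with 6 false calls (4.14 percent of calls). The noise there was independent between probes, with no replicate or slide effect, so these shares are not the error rates of the real comparison.

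The other settings chosen in advance were scaling by the 75th percentile or the median, no filter on dim probes, a filter on all 8 arrays, software spot marks ignored, the series table, eBayes with trend and robust, array weights, the replicate block, leaving out each array, 1 probe per gene, an estimated correlation, fry, and, for the number of detected probes only, a detection rule of 3 of the 4 arrays. Chosen after seeing the data were mean spot brightness, 2 other detection rules (the spot found; 70 percent of pixels over background), cyclic loess, leaving out both arrays numbered 4, the lists as first worded, scaling to the spike-in control probes, and array weights estimated gene by gene. A planned quantile normalization of the processed signal was not run, since that column is not in the files.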

Results

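Gene expression was measured in siliques with developing seeds, as the tissue label states, of Brassica napus line DH12075, 2 days after pollination, on 8 one-colour arrays. The groups were 4 arrays of wild type and 4 arrays of Bntt16 RNAi, plants in which RNA interference is directed at the rape homologues of TRANSPARENT TESTA16 (BnTT16s). In the wild-type arrays numbered 1 to 4, the median foreground minus background was 118, 201, 159 and 114 intensity units. In the Bntt16 RNAi arrays it was 128, 264, 264 and 165 units. Between 49.5 and 54.1 percent of the 43603 probes were well above background on the wild-type arrays, and between 51.8 and 57.7 percent on the Bntt16 RNAi arrays. All 4 arrays of a group detected 16506 probes in wild type and 18143 in Bntt16 RNAi. Correlation across probes, which are not independent replicates, was 0.888 to 0.971 within wild type and 0.886 to 0.981 within Bntt16 RNAi. Between groups it was 0.858 to 0.950 for arrays of the same number and 0.843 to 0.939 for the others. The first principal component (36.1 percent of the variance) separated the genotypes, and the second (29.6 percent) separated the arrays by replicate number in both groups.

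The comparison asks which genes differ at this stage between wild type and plants with RNAi directed at BnTT16s. Each genotype lay on its own slide, so it cannot tell an effect of the RNAi from a difference between slides. The tested early enzymes of flavonoid synthesis, a pathway that also leads to seed coat pigment, were lower in Bntt16 RNAi. Chalcone synthase, its first committed enzyme, fell 4.31-fold (log2 difference −2.11, SE 0.21, n = 4 per group) and flavanone 3-hydroxylase fell 3.85-fold (−1.94, SE 0.12). Most enzymes of the branch to the pigment had no tested probe. The chalcone synthase probe was well above background on only 1 of the 4 Bntt16 RNAi arrays, so the size of its fall is uncertain. A class II small heat shock protein rose 9.59-fold (3.26, SE 0.13), and a chitinase, an enzyme that degrades the chitin of fungal walls, rose 9.33-fold (3.22, SE 0.12). The defence marker PR1 rose 3.54-fold (1.82, SE 0.15). Floral MADS-box genes rose on some of their probes: SEP1 on 2 of 3 (at most 1.7-fold), SEP2 on 1 of 2 (1.69-fold) and AP1 on its only tested probe (2.1-fold). Pectinesterase 5, the 1 tested gene of the pollen list, fell 8.3-fold (−3.05, SE 0.29) and was well above background on only 1 of the 4 Bntt16 RNAi arrays, so the size of its fall is uncertain. No probe was described as TRANSPARENT TESTA16 (0 probes), so the level of the RNAi target is not given.

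Of 20829 tested probes, 4217 (20.2 percent) passed limma's adjusted threshold, 1996 higher and 2221 lower in Bntt16 RNAi, and 1177 of them differed at least 2-fold, 679 higher and 498 lower. Of the 4217, 1180 had an informative name. The median absolute log2 difference of the 4217 was 0.76. The median signed difference of all tested probes, −0.03, is a different measure and depended on the scaling. In 5556 probes (26.7 percent) all arrays of a genotype lay above all arrays of the other. Chance would give 2.86 percent for exchangeable arrays and probes chosen without regard to group. The pairing check does not bear out the former, and the tested probes were chosen with the real groups. A difference between the slides would also raise the share. With replicate number as a block, 8467 probes passed, 3840 higher and 4627 lower, and 4193 probes passed in both fits with the same sign. The share of higher probes among those that passed, 47.3 percent, was 36.7 percent with scaling to the array median (1543 higher, 2662 lower). Scaled to the spike-in control probes, a setting chosen after seeing the data, it was 89.9 percent (4500 higher, 506 lower), as the median difference of all tested probes moved from −0.03 to 0.35.

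In the list of flavonoid enzymes and transporters, 5 of the 14 probes on the array were tested. Of these 5, 4 fell and none rose, and the same 0 higher and 4 lower held adjusted over the list alone. Their mean log2 difference was −1.41 and their median −1.63 (limma's camera, adjusted p = 0.00123). The call was lost with an estimated correlation (adjusted p = 0.111 with an estimated correlation). Chalcone synthase went from 8.81 ± 0.37 (log2 intensity, mean ± SD, n = 4) in wild type to 6.70 ± 0.27 in Bntt16 RNAi (adjusted p = 4.66e-04). Flavanone 3-hydroxylase fell on both of its probes (log2 differences −1.94 and −1.63, adjusted p = 5.09e-05 and 1.55e-04). Flavonoid 3'-hydroxylase, which adds the hydroxyl group that separates quercetin from kaempferol, fell from 11.60 ± 0.18 to 10.14 ± 0.40 (log2 difference −1.46, adjusted p = 0.00205). In Bntt16 RNAi, chalcone synthase was well above background on 1 of 4 arrays and flavonoid 3'-hydroxylase on 3 of 4. Laccase-15, the TT10 oxidase of seed coat browning, did not pass (0.07, adjusted p = 0.79). No tested probe was assigned to dihydroflavonol reductase, anthocyanidin synthase, anthocyanidin reductase or the transporters of the list. The list therefore does not show whether the branch to the seed coat pigment fell. The only tested regulator, TTG1, had a difference of 0.77 with an SE of 0.58 (adjusted p = 0.398), and its wild-type array 3 lay at 8.16 against 10.74 to 10.86 on the other wild-type arrays. Beside this group, the storage protein and pollen probes moved as follows: napin fell 2.28-fold (log2 difference −1.19, adjusted p = 0.00128), cruciferin stood at 0.63 (adjusted p = 0.0641, and 0.00487 with the replicate block), oleosin at 0.44 (adjusted p = 0.205), and pectinesterase 5 fell (−3.05), also adjusted over the list alone (0 higher, 1 lower).

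**Figure D1:**
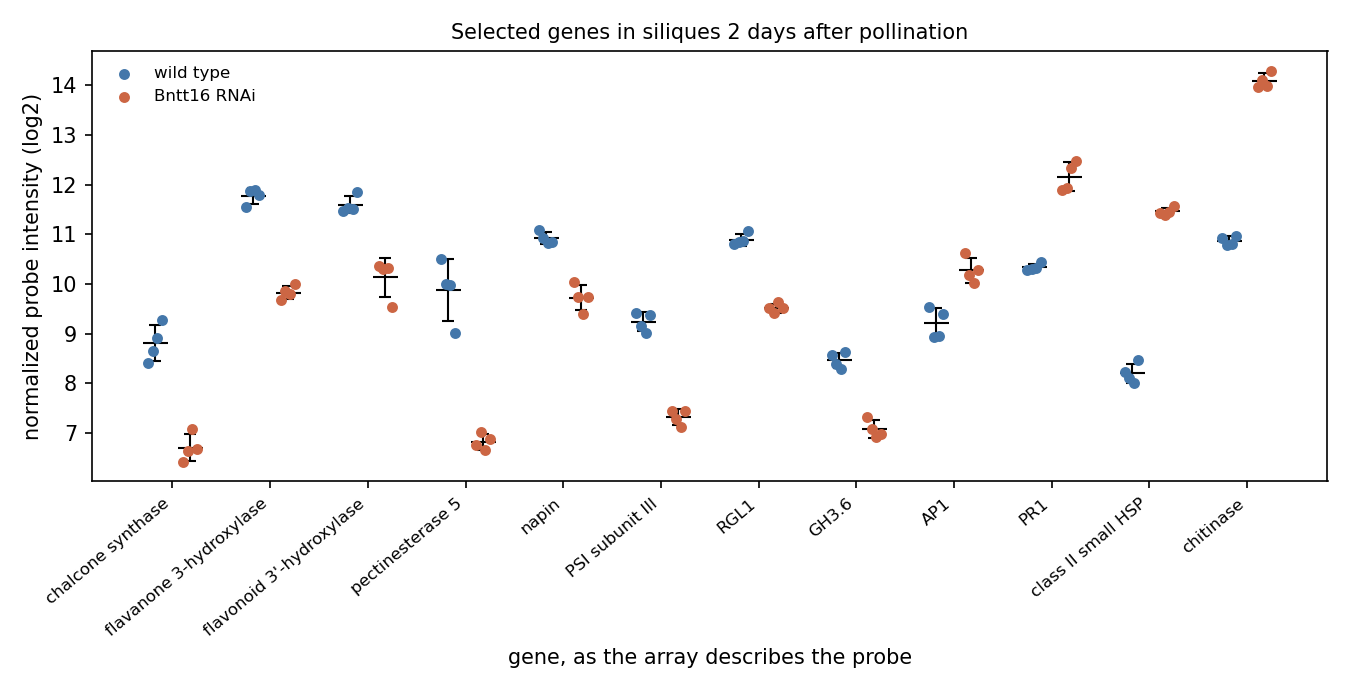
Log2 intensity of 12 genes on each of the 4 wild-type and 4 Bntt16 RNAi arrays, with the mean and SD of each group. Chalcone synthase is lower in all 4 Bntt16 RNAi arrays (means 6.70 against 8.81) and the chitinase is higher in all 4 (14.09 against 10.87).

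Among phenylpropanoid and lignin enzymes, 4 of 13 tested probes fell and none rose over all probes tested, and 1 rose (cinnamoyl-CoA reductase, 0.45) and 4 fell adjusted over the list alone. With the replicate block, 3 were higher and 4 lower: cinnamoyl-CoA reductase (adjusted p = 0.0771, and 0.00864 with the block), caffeoyl-CoA 3-O-methyltransferase (0.37, adjusted p = 0.298, and 0.0201 with the block) and 4-coumarate-CoA ligase 1 (0.29, adjusted p = 0.151, and 0.0289 with the block) rose there. The 4 that fell belong to sinapate ester synthesis, a side branch: sinapate glucosyltransferase fell on 3 probes (log2 differences −1.11, −0.74 and −0.59, smallest adjusted p = 0.00137, on a probe well above background on 3 of 4 Bntt16 RNAi arrays), and sinapoylglucose:choline sinapoyltransferase (SNG2) fell by 0.69 (adjusted p = 0.0433). The last call was lost when any array but Bntt16 RNAi 1 was left out (adjusted p = 0.0502 to 0.0934 without those arrays, and 7.35e-04 to 0.386 over all its alternatives). Phenylalanine ammonia-lyase, cinnamate 4-hydroxylase and the other entry enzymes did not pass, and the list did not pass camera (mean −0.08, adjusted p = 0.772). The counts of 0 higher and 4 lower also held with 75th percentile scaling, median scaling and the series table. With spike-in scaling 2 were higher and 1 lower (median of the list −0.06 here, and 0.40 there).

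All 12 tested MADS-box probes had a positive difference, though 1 lay below 0 with 75th percentile scaling, median scaling and the series table. Of the 12, 4 passed the threshold, and 4 also adjusted over the list alone (mean 0.45, median 0.49, camera adjusted p = 0.00399). The list was lost with an estimated correlation (adjusted p = 0.111 with an estimated correlation), and 7 of its probes passed with the replicate block. SEP1 and SEP2, which act with other MADS-box proteins in flower organ and ovule identity, rose by 0.77 (adjusted p = 0.00423) and 0.76 (adjusted p = 0.00522) on 1 probe each, and a second SEP1 probe rose by 0.51. The third SEP1 probe did not pass (0.50, adjusted p = 0.352, and 0.0165 with the block), and the other SEP2 probe stood at 0.07 (adjusted p = 0.706). AP1, known for sepal and floral meristem identity, rose from 9.21 ± 0.30 to 10.28 ± 0.25 (adjusted p = 0.00604). The fruit gene SHP1 had a difference of 0.62 (adjusted p = 0.0939, and 0.0144 with the block).

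In the defence and jasmonate list, 2 of 3 tested probes rose and none fell, also adjusted over the list alone (2 higher, 0 lower). PR1 went from 10.34 ± 0.07 to 12.16 ± 0.29 (adjusted p = 1.90e-04), and lipoxygenase 2, an enzyme of jasmonate synthesis, rose 1.64-fold on 1 probe (adjusted p = 0.0103). Its other probe had a difference of 0.21, of uncertain size because this probe was saturated on all 4 Bntt16 RNAi arrays (16.00 ± 0.00). The list passed camera (mean 0.92, adjusted p = 0.0215) but not with an estimated correlation (adjusted p = 0.111 with an estimated correlation) or the replicate block (adjusted p = 0.065; 9.35e-05 to 0.125 over all its alternatives). In the heat shock list, 4 of 13 probes rose and 1 fell, with the same 4 and 1 adjusted over the list alone. All 4 that rose encode cytosolic small heat shock proteins, which bind unfolded proteins: the class II protein went from 8.20 ± 0.20 to 11.46 ± 0.08 (adjusted p = 6.38e-06), and 3 class I probes rose by 0.74, 1.06 and 1.72, the last on a probe well above background on 3 of 4 wild-type arrays. The probe that fell was 1 of 6 for HSP70 (−0.65, adjusted p = 0.00942), and HSP101 did not pass (−0.20). The list was at the limit of camera (mean 0.50, adjusted p = 0.0495), at adjusted p = 0.505 with an estimated correlation, at 0.129 with the replicate block, and at 0.722 with 1 probe per gene (0.00214 to 0.722 over all its alternatives). It also failed without wild type 2, 3 or 4 or Bntt16 RNAi 2 or 4 (adjusted p = 0.0536 to 0.0936). Its median, 0.20 here, was 0.00 with scaling to the 75th percentile and −0.03 with scaling to the median. The cold and drought list had 1 tested probe, COR25, with a difference of 0.23 (adjusted p = 0.596).

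Among auxin genes, 4 of 13 probes rose and 4 fell, and the same numbers held adjusted over the list alone (camera adjusted p = 0.824), with 5 higher and 4 lower under the replicate block. The numbers depended on scaling: 1 was higher and 4 lower with 75th percentile scaling and with median scaling. With spike-in scaling, which raised the median of all tested probes, 5 were higher and 2 lower. GH3.6, which conjugates auxin to amino acids, fell 2.61-fold on 1 probe (−1.38, SE 0.13, adjusted p = 3.77e-04; well above background on 2 of 4 Bntt16 RNAi arrays) and stood at −0.30 on its other (adjusted p = 0.158). The efflux carrier PIN7 fell 1.92-fold (−0.94, adjusted p = 0.00362). IAA9 rose by 1.00 (adjusted p = 0.00225) on 1 probe and stood at −0.11 on its other. The probes of IAA7 disagreed: 1 fell (−1.06, adjusted p = 0.00131) and 1 rose (0.58, adjusted p = 0.0495). In the gibberellin list, 3 of 8 probes rose and 1 fell, also adjusted over the list alone (mean 0.15, camera adjusted p = 0.424). The 3 that rose were probes of GASA1, a gibberellin-regulated protein (largest log2 difference 0.90, adjusted p = 8.18e-04), and its other probe stood at 0.28 (adjusted p = 0.262, and 0.0448 with the replicate block). The probe that fell was that of the DELLA repressor RGL1, which went from 10.89 ± 0.12 to 9.52 ± 0.09 (adjusted p = 1.37e-04).

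The photosynthesis list, taken as a marker of the green silique wall, had 5 probes higher and 1 lower of 47, and 4 higher and 1 lower adjusted over the list alone, which left out the PSBO probe (0.42). Phosphoribulokinase rose 2.23-fold on 1 of its 5 probes (adjusted p = 0.00102). Rubisco activase rose by 0.85 (adjusted p = 0.0121) and a photosystem I chlorophyll-binding protein, LHCA3, which passed on 2 of its 8 probes, by 0.60 (adjusted p = 0.00768, on a probe well above background on 3 of 4 wild-type arrays), but neither of these differences (0.85 and 0.60) passed with percentile scaling, median scaling or the series table (adjusted p from 5.75e-06 to 0.0941 and from 2.08e-06 to 0.317 over all alternatives). Photosystem I subunit III fell 3.78-fold on 1 probe (adjusted p = 7.92e-05) and stood at −0.29 on the other. The list passed camera upward (mean 0.21, median 0.23, adjusted p = 0.0361), not with an estimated correlation (adjusted p = 0.111 with an estimated correlation). It failed without wild type 4 or Bntt16 RNAi 2 or 3 (adjusted p = 0.0644 to 0.0884; 0.00107 to 0.935 over all its alternatives). Its median was −0.04 with percentile scaling (2 higher, 2 lower) and −0.08 with median scaling (1 higher, 2 lower). With the replicate block, 15 probes were higher and 2 lower. The secondary wall list, the other wall marker, had no probe past the threshold among 4, over all probes or adjusted over the list alone (0 higher, 0 lower; camera adjusted p = 0.772), and 2 were higher with the block. Both were XCP2 probes (0.41, adjusted p = 0.0595, and 0.0105 with the block; 0.60, adjusted p = 0.288, and 0.00697 with the block), while CESA8 stood at −0.81 (adjusted p = 0.139).

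No seed list passed camera. The 3 tested storage probes gave 0 higher and 1 lower over all probes, and 1 higher (cruciferin) and 1 lower (napin) adjusted over the list alone. Their mean (−0.04) and fry were downward while their median (0.44) and camera were upward (camera adjusted p = 0.919). In fatty acid and triacylglycerol synthesis, 1 probe was higher and 3 lower of 23, also adjusted over the list alone (camera adjusted p = 0.772), and 5 were higher and 9 lower with the replicate block. These counts depended on scaling: 0 were higher and 3 lower with median scaling, and 3 higher and 3 lower with the series table and with cyclic loess. With spike-in scaling, which raised the median of all tested probes, 4 were higher and 0 lower (median of the list −0.17, and 0.23 there). The plastid enzyme stearoyl-ACP desaturase fell on 2 of its 8 probes (log2 differences −0.63 and −0.57, smallest adjusted p = 0.00475), and the other 6 lay from −0.57 to 0.79. KAS3 fell on 1 probe (−0.60, adjusted p = 0.0109) and did not pass on its other (−0.38, adjusted p = 0.177, and 0.0181 with the block). DGAT2, an enzyme of the last step of oil synthesis, rose by 0.58 on 1 of 3 probes (adjusted p = 0.0169; 0.34 and 0.46 on the others), a call lost without Bntt16 RNAi 2 (adjusted p = 0.0604; 1.33e-04 to 0.0628 over its alternatives). No endosperm or seed size probe passed among 3, over all probes or adjusted over the list alone (0 higher, 0 lower, camera adjusted p = 0.824): IKU1 stood at −0.21 and ARF2 at −0.08. The seed coat mucilage list had 1 tested probe (MUM1, −0.17, adjusted p = 0.521), and the nucellus list had 0. In the cell cycle list, 1 of 6 probes fell, also adjusted over the list alone (camera adjusted p = 0.469, fry adjusted p = 0.0444). It was 1 of 2 probes of the replication factor MCM3 (−0.73, adjusted p = 0.024; −0.50, adjusted p = 0.617, on the other), whose call was lost without wild type 1 or 4 or without Bntt16 RNAi 2, 3 or 4 (adjusted p = 0.0533 to 0.0776 without them, and 1.78e-05 to 0.3 over all its alternatives). In the glucosinolate list, 1 of 9 probes fell, also adjusted over the list alone, with a mean of −0.02, a median of 0.05 and camera upward (adjusted p = 0.772), and 3 were higher and 1 lower with the replicate block. The probe that fell was 1 of 3 for the transporter GTR1 (−1.24, adjusted p = 0.0236; 0.30 and 0.05 on the others; well above background on 3 of 4 Bntt16 RNAi arrays), lost without wild type 2, 3 or 4 or without Bntt16 RNAi 2 (adjusted p = 0.0581 to 0.0634 without them, and 5.03e-06 to 0.0961 over all its alternatives).

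**Figure D2:**
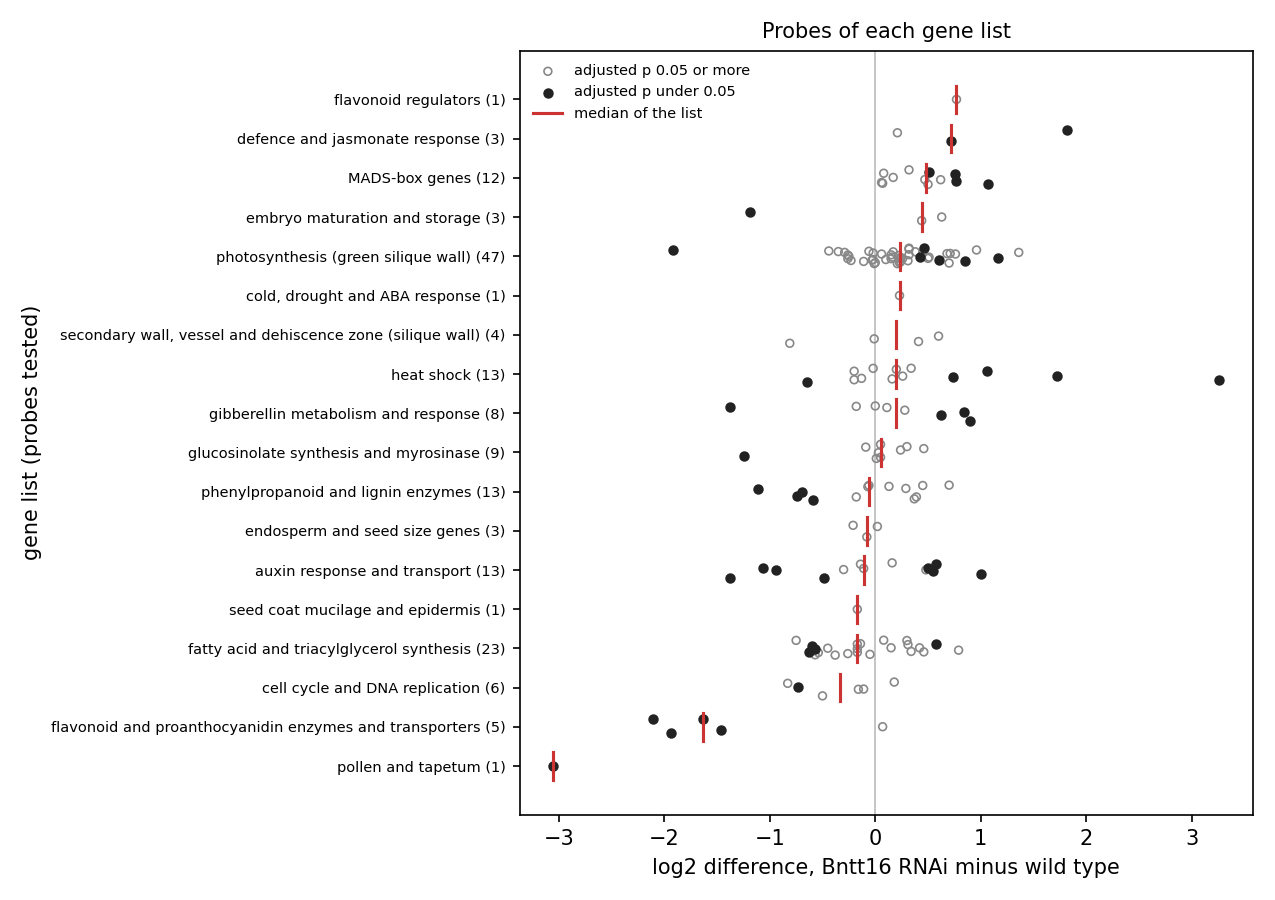
Log2 difference (Bntt16 RNAi minus wild type) of each tested probe, grouped by list, with filled points for adjusted p below 0.05 and a red line at the median of each list. The 5 flavonoid enzyme probes have a median of −1.63 and the 12 MADS-box probes, all above 0 here and 1 below 0 with 75th percentile scaling, median scaling and the series table, a median of 0.49.

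Outside the lists, the largest rises and falls are those of named genes that met the selection of the methods, which includes signal well above background on all 8 arrays. The rises were led by the chitinase (adjusted p = 5.31e-06), while a second chitinase probe (3.37) and a cathepsin B-like probe (3.48) lay higher without meeting that selection. Extensin-3, a cell wall glycoprotein, rose by 2.85 (SE 0.46), a peptidyl-prolyl isomerase by 2.21 (SE 0.09), a B12D protein by 2.18 (SE 0.22), and a basic glucanase by 2.17 (SE 0.11, adjusted p = 1.74e-05). An actin probe rose by 2.16 (SE 0.39) and glutathione S-transferase 6, of the detoxification enzymes, by 2.02 (SE 0.12). The falls were led by a histone H3.2 probe (−2.04, SE 0.60, adjusted p = 0.0454) and the ribosomal protein L29-2 (−1.95, adjusted p = 6.54e-05). The L29-2 probe was saturated on 1 wild-type array (wild-type mean 15.73), so the size of its fall and its place behind histone H3.2 are uncertain. An MS5-like protein followed (−1.75), then HOTHEAD (−1.72, SE 0.46), the homeobox gene HAT1 (−1.71), an expansin (−1.71, SE 0.10), which loosens cell walls, and a strictosidine synthase family protein (−1.69). S-adenosylmethionine synthetase stood at −1.62 and a light regulated protein at −1.61, both past the threshold. The histone H3.2 call was lost without any wild-type array or Bntt16 RNAi 2 (adjusted p = 0.0659 to 0.104 without them, and 1.10e-05 to 0.104 over all its alternatives). The HOTHEAD call was lost without wild type 1, 2 or 3 or Bntt16 RNAi 2 or 3 (adjusted p = 0.0569 to 0.0859 without them, and 8.87e-06 to 0.0859 over all its alternatives). Of the probes with no usable name, A_46_P242339 fell 22.7-fold (−4.50, SE 0.15, adjusted p = 3.74e-06), and A_46_P348015 rose by 2.68 (SE 0.43, adjusted p = 0.00353).

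Some genes passed while below background on every array of a genotype, where the fold is a lower bound. Below background in wild type, squalene monooxygenase, an enzyme of sterol synthesis, was at least 7.2-fold higher in Bntt16 RNAi (adjusted p = 1.15e-05). A tobacco-described NtEIG-E80 protein was at least 3.87-fold higher and glutamate decarboxylase 4a at least 3.71-fold higher. Below background in Bntt16 RNAi, a pectinesterase-like protein described from pollen was at least 5.67-fold lower (adjusted p = 2.97e-05) and a cystatin-domain protein at least 5.56-fold lower. The seed-specific protein Bn15D80B was at least 2.63-fold lower and expansin-A22 at least 2.36-fold lower. Probe A_46_P170804, with no usable name, was at least 9.85-fold lower. In all, 126 probes passed while below background on all wild-type arrays and 47 while below background on all Bntt16 RNAi arrays. Such a probe was tested only where all 4 arrays of the other group detected it, so the filter largely set its direction. The Bntt16 RNAi arrays also detected more probes (18143 on all 4, against 16506 in wild type), so the 2 counts do not compare the genotypes.

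All wild-type arrays lay on 1 slide and all Bntt16 RNAi arrays on the other, so slide and genotype cannot be told apart in any of these differences. Without Bntt16 RNAi 2 the count of probes fell to 2574, and without wild type 2 to 2768.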

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

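Of the tests in this part, those on seed gene lists, storage proteins and stress families were chosen only after the result was seen, and those on splits of the arrays, neighbouring spots and spike-ins were chosen before any group was compared.

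A single array stood apart from the other 3 of its group in 13 of the 140 groups examined, where chance alone flags about 1 in 20, or 7. The values are the gap to the nearest array divided by the range of the group. In wild type, array 4 stood apart for PR1 (0.838; 10.44 against 10.29 to 10.32), flavonoid 3'-hydroxylase (0.875; 11.86 against 11.48 to 11.53) and A_46_P348015 (0.903; 7.57 against 9.39 to 9.58). Array 3 did so for TTG1 (0.955; 8.16 against 10.74 to 10.86) and actin (0.839; 8.60 against 7.84 to 7.96), and array 1 for the light regulated protein (0.921; 10.24 against 9.97 to 9.99). In Bntt16 RNAi, array 4 stood apart for flavonoid 3'-hydroxylase (0.936; 9.54 against 10.31 to 10.36), CESA8 (0.893; 8.05 against 9.46 to 9.62) and A_46_P277543, a probe with no usable name (0.889; 9.29 against 8.82 to 8.87). Array 3 did so for XCP2 (0.932; 11.92 against 12.17 to 12.19) and squalene monooxygenase (0.840; 10.24 against 9.84 to 9.91), array 2 for stearoyl-ACP desaturase (0.947; 10.03 against 10.20 to 10.21), and array 1 for expansin-A22 (0.905; 6.42 against 6.12 to 6.15).

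If replicate number is disregarded, only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many probes past the threshold (4217, highest other 1). The same held for the probes at least 2-fold apart (1177, highest other 1, with 1 split as large). This share lies under the bound of 0.05 named beforehand, but it takes the arrays as exchangeable, which the pairing check does not bear out. The tested probes were also chosen with the real groups, which favours the real split. A difference between the 2 slides would set the real split apart as well. For the lists the real split gave 5 and the highest other 4, with 1 split as large. If the arrays are taken as paired by replicate number, only the 8 splits that part all 4 pairs, as the real one does, compare with it, and they are too few for a share under 0.05. Among them the real values were 4217, 1177 and 5 and the highest others 0, 0 and 4, while the remaining splits keep at least 1 pair together.

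The large number of changed probes was set against technical differences between the slides. Stains or gradients remain open: log2 differences of probes side by side correlated at 0.095 (SE 0.010, 10345 pairs), under the bound of 0.1 named beforehand but not by 2 standard errors, a margin asked for after the value was seen. A signal-dependent difference in labelling or hybridisation also remains open. The 4 of 10 spike-ins above background on all 8 arrays were all lower on the Bntt16 RNAi slide (−0.28, −0.36, −0.43 and −0.30), with a median size of 0.33 against 0.76 for the changed probes, between the bounds named beforehand. That median measures an offset and not a dependence on signal. At wild-type means of 13.26, 8.91, 10.37 and 11.28, in the same order, the 4 differed by similar amounts. Whether the same amount of spike-in was added to each sample is not given in the sources used here.

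The lower flavonoid enzymes could come from a lower share of seed RNA in the siliques. Over 29 seed probes outside the pathway the median log2 difference was −0.14 (bootstrap SE 0.11, 2000 draws), above the bound of −0.82 set midway between 0 and the flavonoid median of −1.63. As first read, this counted against the explanation, but after the result was seen it was read as excluding nothing, because 23 of the 29 probes are fatty acid enzymes, which are not restricted to seeds. A narrower test on storage proteins, added after that, gave a median of 0.44 over 3 probes, too few to decide. The 3 went both ways (napin −1.19, cruciferin 0.63, oleosin 0.44), and the probes of cruciferin and oleosin were dimmer (wild-type means 8.09 and 8.10) than that of napin (10.92). The seed-specific protein Bn15D80B, outside these lists, was at least 2.63-fold lower. It was named because of its fall, so it does not decide the question. Whether storage protein genes follow the seed share 2 days after pollination was not tested. A lower seed share, a difference between slides, and an effect of the RNAi on the pathway cannot be told apart, since no tested list was shown to follow the seed share and no slide held both genotypes.

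The higher defence genes and small heat shock proteins could reflect a general stress response of these plants, although the wider family of 80 heat shock and chaperone probes did not pass (16 higher, 13 lower, median 0.00, camera adjusted p = 0.661). That balance depended on scaling: 12 were higher and 16 lower with median scaling, and 22 higher and 3 lower with spike-in scaling (median 0.40). Of 4 stress families, 2 passed camera upward, WRKY factors (adjusted p = 0.00261) and glutathione S-transferases (adjusted p = 0.0144), while peroxidases (adjusted p = 0.766) and chitinases with glucanases (adjusted p = 0.813) did not. The family of chitinases with glucanases also holds endo-1,4-beta-glucanase, a cell wall enzyme, so its result does not count against a stress response. For a stress response, the rule asked for positive medians in all 4 families and at least 3 of them past camera. At most 1 with camera's p under 0.05 upward would have counted against it. The result of 2 lies between these bounds, so the test leaves this explanation open. With an estimated correlation none of the 4 passed (WRKY factors adjusted p = 0.0896 with an estimated correlation, glutathione S-transferases 0.0997). A difference between the slides, or between benches or days of growth, could not be tested, because by design 0 slides hold both genotypes. These explanations and an effect of the RNAi itself cannot be told apart, and the labels name a greenhouse or growth chamber without saying which plants grew where.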

How the results depend on the processing

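Tests chosen only after seeing the data were spike-in scaling, cyclic loess, weights estimated gene by gene, both arrays numbered 4 left out, mean brightness, 2 detection rules and the lists as first worded. The 4217 probes past the threshold became 14239 with array weights, whose default estimate did not converge (weights 0.25 to 51.8), and 9586 with weights estimated gene by gene (0.379 to 7.26). The replicate block gave 8467. Leaving out 1 array gave 2574 (without Bntt16 RNAi 2) to 3882, with 2768 without wild type 2; fewer arrays were used there. The 1177 probes at least 2-fold apart became 635 when only probes above background on all 8 arrays were used, which were fewer, 1946 with spike-in scaling, and 1086 to 1287 with 1 array left out. Without both arrays numbered 4, 3639 probes passed, 1240 at least 2-fold. Every other alternative run on these counts kept both within 1.5 times, and the rule of 3 of the 4 arrays was run only on the number of detected probes.

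The 5 lists past camera became 2 with 75th percentile scaling, 2 with median scaling, 2 with probes above background on all 8 arrays (where the flavonoid list had too few probes to be tested), 2 with the series table and 2 with spike-in scaling. They became 3 with array weights, 3 with the replicate block, 3 with cyclic loess, 3 with 1 probe per gene and 3 with the lists as first worded (the defence list untested in both), 4 without both arrays numbered 4, and 0 with an estimated correlation. With 1 array left out they were 3 to 5, with 3 without wild type 4 and 3 without Bntt16 RNAi 2. The flavonoid and MADS-box lists were lost only with the estimated correlation among the alternatives that tested them (adjusted p 7.01e-06 to 0.111 and 8.25e-04 to 0.111 over their alternatives). The defence list was lost in 8 of 26 alternatives, the heat shock list in 17 of 28 and the photosynthesis list in 11 of 28. The mean of the photosynthesis list, 0.21, was −0.04 with median scaling, against a median of −0.10 for all probes. With fry, which does not compare a list with other genes, 6 lists passed. The cell cycle list passed only there (adjusted p = 0.0444; 0.0444 to 0.776 over its alternatives).

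Of the 59 named probes past the threshold, 47 kept sign and call under every alternative that tested them, 12 lost the call under some and 0 reversed. PIN7, stearoyl-ACP desaturase, KAS3 and the HSP70 probe lost it only with spike-in scaling. Among the lists and the genes selected by the naming rule, the block changed the calls of the defence list, the heat shock list and XCP2 only. Further probes of the lists passed with it, among them SHP1, cruciferin and cinnamoyl-CoA reductase, as given with those genes. For changes other than those from fewer probes or arrays, the cause was not tested. Quantile normalization of the processed signal was not run, a slide block could not be fitted, and TRANSPARENT TESTA16 had no probe. Signal over background limits which genes can be seen: 17344 probes were well above background on no wild-type array and 16057 on no Bntt16 RNAi array.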

Other observations

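All tests in this part were chosen only after the result was seen: genes were grouped into 25 families by description, and each family was tested with limma's camera. Of these, 8 passed, and the lowest adjusted p among the others was 0.204.

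Genes for ribosomal proteins, histones and expansins were lower in Bntt16 RNAi. Of 239 probes described as 40S or 60S ribosomal proteins, 77 fell and 2 rose, and 206 had a negative difference (median −0.48, camera adjusted p = 1.12e-11, and adjusted p = 0.00431 with an estimated correlation). Of the 77, 1 is described as a mitochondrial precursor (S10, −1.02). Of 79 probes whose description names a histone, 5 of them for histone-lysine methyltransferases, which did not pass, 39 fell and 1 rose (median −0.61, adjusted p = 1.20e-10, and adjusted p = 0.0164 with an estimated correlation), among them histones H2A (−1.14) and H4 (−1.36). Of 11 expansin probes, 8 fell and none rose (median −0.93, adjusted p = 3.80e-06, and adjusted p = 0.0455 with an estimated correlation), such as expansin-A14 (−1.44). All 11 were below 0 here and 1 lay above 0 with spike-in scaling. Of 47 tubulin and kinesin probes, 15 fell and 1 rose (median −0.40, adjusted p = 1.44e-04), but not with an estimated correlation (adjusted p = 0.115 with an estimated correlation), and the median was 0.02 with spike-in scaling. With that scaling, which moved the median of all probes to 0.35, the medians were −0.22 for ribosomal proteins, −0.48 for histones and −0.61 for expansins. The proteasome family did not pass (0 higher, 3 lower of 46, adjusted p = 0.204).

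Other families were higher. Of 9 probes whose description holds the words cysteine proteinase, 4 rose and none fell (median 0.60, adjusted p = 6.41e-04, and adjusted p = 0.0455 with an estimated correlation). All 4 were described as cathepsin B-like, and the largest differences were 3.48, 2.88 and 1.12, the first 2 on probes well above background on 2 and 3 of the 4 wild-type arrays. By its definition this family takes in inhibitors whose description holds the words cysteine proteinase. Inhibitors described as cystatins are not in this family, and the cystatin-domain protein given above fell. Of 8 WRKY transcription factor probes, a family known for roles in defence, 4 rose and none fell (median 0.78, adjusted p = 0.00261, and adjusted p = 0.0896 with an estimated correlation): WRKY33 (0.91), WRKY11 (0.64), WRKY4 (0.60) and WRKY31, below background on all wild-type arrays and at least 1.31-fold higher. Of 10 glutathione S-transferase probes, 4 rose and none fell (median 0.24, adjusted p = 0.0144, and adjusted p = 0.0997 with an estimated correlation), with medians of −0.07, −0.11 and −0.04 under 75th percentile scaling, median scaling and the series table. Of 27 MYB probes, 4 rose and 1 fell (median 0.19, adjusted p = 0.0485, and adjusted p = 0.311 with an estimated correlation), among them MYB21 (1.77; well above background on 3 of 4 wild-type arrays). Chitinases and glucanases went both ways, 5 higher and 7 lower of 22: 2 chitinase probes rose by 3.22 and 3.37 (the latter well above background on 3 of 4 wild-type arrays), while endo-1,4-beta-glucanase, a cell wall enzyme grouped with them, fell by 1.33. With spike-in scaling 7 of the family were higher and 3 lower (median −0.32 here, and 0.08 there).

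Of 9 probes described from pollen, anther or tapetum, 77.8 percent lay below 0, 2 fell and 1 rose (limma's camera, adjusted p = 0.253), and a test for less pollen RNA in the siliques was left undecided by these values. Pollen-expressed protein MF6t was at least 2.54-fold lower and a pollen coat protein at least 1.57-fold higher. The median of the 9, −0.28, was −0.37 to −0.25 with 75th percentile scaling, median scaling, the series table and cyclic loess, and 0.09 with spike-in scaling, which moved the median of all probes to 0.35.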
